A study of Mus musculus with 12 samples.

How the data were processed

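RNA sequencing of Neuro-2a cells transfected with a control small RNA, a miR-155 mimic or a miR-155 inhibitor gave 12 libraries, 4 per group, which were placed in groups by the treatment named in the labels. Total RNA was extracted and libraries were made with a VAHTS kit, per the labels' protocols. The authors deposited a table of whole-number read counts per gene and a table of TPM values for the same 15767 genes. Per the submitters' processing notes, fastp, STAR, featureCounts, StringTie and edgeR were used with the genome build GRCm39. Their versions, roles and order, the annotation release, the strandedness and any filter on genes are not given in the sources used here. The deposited TPM values sum to the same total in each library.

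Total counts ran from 60695388 to 74200532 per library. A floor of 3 counts is given where a gene had 0 counts, and such floors cover counting error only, while 95% intervals of fold changes and site scores rest on the spread between libraries. The labels do not say that the 4 libraries of a group came from separate cultures on separate days, so p-values measure the spread between these samples, which may be technical. Within groups, libraries differed by a chi-square of 10.9 to 103 per degree of freedom over genes, so 0 pairs were taken as copies of one library.

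Gene symbols came with the deposited tables for 15499 genes, from a name table for 260, and 8 had none. The reference used here, GRCm38 with GENCODE release M21, differs from the authors' build. It served only for 3' UTR sequence, GC content, length and which genes overlap on the same strand, matched by gene identifier for 15738 genes, and no coordinates are reported. Genes that overlap on the same strand, paralogs and antisense genes are uncertain, since how reads were divided between them is not known.

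The groups, tests, gene lists, named-gene rule and alternatives were chosen before the data were examined, except where a choice is said to have been made after seeing the data. The counts were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled with TMM, genes were filtered with filterByExpr, leaving 13014, and a quasi-likelihood model with robust dispersions was fitted to all 12 libraries with group as the only term. The contrasts were mimic against control, inhibitor against control and mimic against inhibitor. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values use the scaled library sizes, except those of genes called only by DESeq2 or under another setting and of overlapping pairs, which use total counts.

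The rule for named genes took, among called genes with a mean of at least 2 CPM, no overlap between groups and an approved symbol, those with the greatest log2 fold changes. With fewer than 10 called, as happened in each contrast, it took the 10 genes of smallest p under the same filters, so their separation of the groups is part of their selection. The 4 study axis genes were always named, and up to 4 members of each list described. Some genes that the rule takes are not reported here. No 8mer gene met the rule for naming seed-site genes that were lower in mimic.

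The 24 gene lists covered the study axis, mitochondrial fission and fusion, mitochondrial biogenesis regulators, nuclear OXPHOS subunits, mitochondrially encoded mRNAs, fatty acid oxidation, the TCA cycle, glycolysis, mitophagy and autophagy, antioxidant response, hypoxia response, integrated stress and unfolded protein response, interferon-stimulated genes, NF-kB and inflammatory genes, p53 and apoptosis, cell cycle, cholesterol synthesis, neuronal identity, reported miR-155 targets, the small RNA pathway, cytosolic ribosomal proteins, and markers of fibroblast and mesenchymal, glial, and immune and endothelial cells. Some genes stand in more than 1 list. The 23 with measured members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists within each contrast. They were also tested with an estimated correlation and with fry. Seed sites were 8mer (AGCATTAA), 7mer-m8 (AGCATTA) and 7mer-A1 (GCATTAA) matches in the longest annotated 3' UTR of 15491 genes.

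The edgeR steps were tested on simulated data for mimic against control, with 13014 genes, 3 simulations and 50 changed genes per fold. They recovered 10% of genes changed 1.25-fold, 54% of genes changed 1.5-fold, 95.3% of those changed 2-fold and 98.7% of those changed 4-fold. A mean of 5.67 unchanged genes was called. All changed genes were drawn from those above 10 CPM, so recovery at lower levels was not simulated. With no gene changed, in a single simulation, 4.69% of genes had p under 0.05 and 0 were called. In the real mimic against control comparison the share was 0.546%. The simulated libraries lacked the differences by replicate number, so the recovery above may not hold for the real libraries. When the 401 8mer genes were lowered by 0.1 on the log2 scale, the recovered shift was -0.12, and with none lowered it was -0.0174, each in a single simulation. Genes were drawn independently, so these values do not show what shift the real libraries could reveal. There the 95% interval of the 8mer score difference between mimic and control was -0.141 to 0.2, which holds a lowering of 0.1.

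Alternatives tried were RLE and upper-quartile scaling, no filter and a 1 CPM filter, DESeq2 1.42.0, fits of 8 libraries, the replicate number as a block, limma with trend on log2(TPM + 1) and log2(TPM + 0.1), non-robust dispersions, stricter thresholds, leaving out each library in turn, other 3' UTR definitions and genes of at least 10 CPM. Alternatives added after seeing the data were replicate numbers 1 to 3 alone, number 4 as a batch term, leaving out genes that switch between libraries, offsets for gene length and GC content per library, and a simulation in which the controls were drawn too.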

Results

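RNA was sequenced in 12 libraries from Neuro-2a, a mouse neuroblastoma cell line used as a neuron-like model. The labels put 4 libraries in each of 3 groups: a control small RNA, a miR-155 mimic, meant to supply the microRNA, and a miR-155 inhibitor, meant to block it. The values used here do not measure miR-155 or the uptake of the reagents. An absence of called genes therefore cannot tell an inactive reagent from a lack of response. Cells were transfected without serum or antibiotics, given growth medium after 4 h and cultured to day 2. Total counts per library ran from 60695388 to 74200532, and 13669 to 13836 genes had at least 1 count in a library. The series title names a question about miR-155 and the genes Pparg, Ppargc1a, Esrra and Dnm1l, which encode PPARγ, PGC-1α, ERRα and the mitochondrial fission GTPase Drp1.

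For Pparg, Esrra and Dnm1l, each 95% interval of a difference between groups included 0. Pparg, a lipid-sensing nuclear receptor, measured 20.6 ± 2.41 CPM in control, 19.8 ± 3.97 in mimic and 18.1 ± 3.99 in inhibitor (SD, n = 4 each). Esrra, an orphan nuclear receptor of energy metabolism, measured 97.1 ± 22.3, 88.8 ± 9.91 and 92.4 ± 11.2 CPM in the same order. Dnm1l measured 72.8 ± 19.6, 73.2 ± 7.13 and 69.9 ± 6.61 CPM. In mimic against control the log2 fold changes were -0.05 for Pparg (95% interval -0.42 to 0.31), -0.13 for Esrra (-0.46 to 0.20) and 0.01 for Dnm1l (-0.35 to 0.37). In inhibitor against control they were -0.18 for Pparg (-0.55 to 0.18), -0.07 for Esrra (-0.40 to 0.26) and -0.06 for Dnm1l (-0.42 to 0.30). Each had an adjusted p of 1 by edgeR. By replicate number, looked at after seeing the data, Pparg was lower in inhibitor than in control at 4 of 4 numbers (14.5 against 19.3 CPM, 16.1 against 18.7, 18.2 against 20.2 and 23.6 against 24.0). The mean difference of -2.46 CPM exceeded the SD of control (2.41) but not that of inhibitor (3.99). The exact two-sided permutation test of the groups gave p = 0.257 for this gene, and an adjusted p of 0.971 over the 9 tests of these genes. That test took no account of the number. With the number as a block its log2 fold change was -0.20 (unadjusted p = 0.0414), and over the alternatives its adjusted p by edgeR, DESeq2 or limma ran from 0.962 to 1. Ppargc1a, a coactivator of mitochondrial biogenesis, had 5 counts in control 2 and 0 in the other 11 libraries, where 3 counts correspond to 0.0404 to 0.0494 CPM, so a difference was not detectable at this depth. The sign of the Dnm1l value in mimic against control depended on single libraries, and it was -0.15 without control 2, -0.02 without control 3, -0.02 without mimic 4, -0.01 without mimic 2 and -0.0035 without mimic 1. That of Pparg turned to 0.03 without control 4 and 0.05 without mimic 2. In inhibitor against control, Dnm1l turned to 0.04 without control 1 and 0.05 without control 4, and Esrra to 0.05 without control 2 and 0.01 without inhibitor 4.

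**Figure D1:**
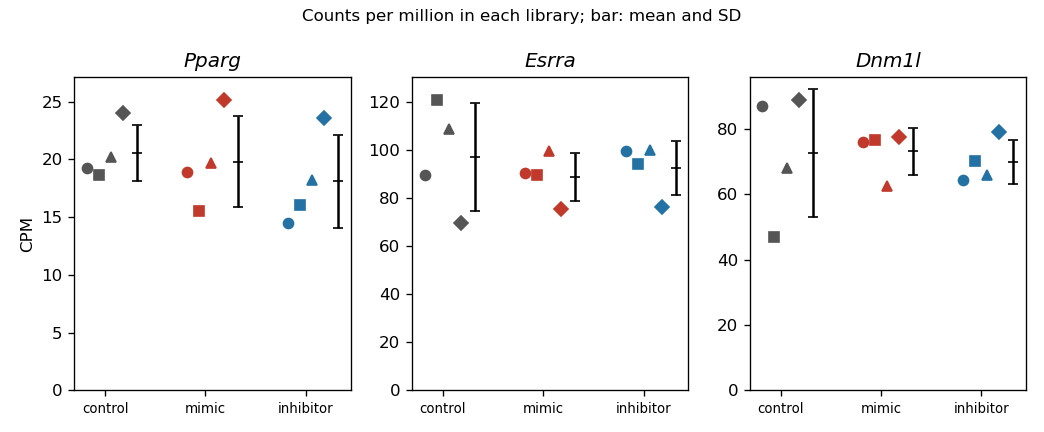
CPM (vertical axis) of Pparg, Esrra and Dnm1l in each library of the control, mimic and inhibitor groups; circles, squares, triangles and diamonds are replicate numbers 1, 2, 3 and 4, and each bar is the mean ± SD of 4 libraries. The groups overlap for each of the 3 genes, and the diamonds are the lowest Esrra values in each group.

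The mimic was compared with control to ask which genes respond to added miR-155, and 0 of the 13014 genes tested by edgeR passed an adjusted p of 0.05. Among the genes nearest to the threshold, Phactr2, a phosphatase and actin regulator, measured 7.10 ± 0.65 CPM in mimic and 5.45 ± 0.711 in control (SD, n = 4 each). Eef1akmt2, a lysine methyltransferase, had a log2 fold change of 0.34 and Naif1, a nuclear apoptosis-inducing factor, one of 0.25. Lower means in mimic were found for Pbx4, a homeobox transcription factor (-0.30), Hrh1, the histamine H1 receptor (-0.30), Med18, a Mediator subunit (-0.22), Necab2, a neuronal calcium-binding protein (-0.42), Sorbs3, a cell adhesion adaptor (-0.36), Scarf2, a scavenger receptor (-0.29), and Sft2d1, a vesicle transport protein (-0.27). Each of these 10 had an adjusted p of 1 by edgeR.

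For this comparison, 71 genes had an unadjusted two-sided p under 0.05, where 651 would be met by uniform p-values. DESeq2 called 3 genes (122 at an unadjusted p under 0.05) and limma on log2(TPM + 1) called 0 (108). The DESeq2 calls, named after their values were seen, were Gm49378, Gm45062 and Mss51. Gm49378 measured 2.13 to 2.91 CPM in the 4 mimic libraries and 41.9, 3.74, 40.6 and 34.2 CPM in controls 1 to 4. It overlaps Ipo4, an importin gene, on the same strand, an overlap looked up after the call, and across libraries the sum of both genes varied 1.16-fold. Mss51 was at 0 in the mimic libraries, where 3 counts correspond to 0.0407 to 0.0481 CPM, and at or under 0.524 CPM in the others. Gm45062, which edgeR's filter left out, stood at 6.04, 5.98 and 4.2 CPM in control 1, control 3 and inhibitor 1 and at 0 in the other 9 libraries, 4 of them mimic. There 3 counts correspond to 0.0407 to 0.0494 CPM. It overlaps Glcci1 on the same strand, with a correlation of -0.281 across libraries and a sum that varied 1.66-fold. By edgeR the adjusted p of Gm49378 was 0.257, and without control 2 it passed as the 1 gene called there, with a log2 fold change of -3.96. With replicate numbers 1 to 3 alone, or with number 4 as a batch term, both chosen after seeing the data, edgeR called 0 genes, with 379 and 223 at an unadjusted p under 0.05. The unadjusted count was 121 without control 1, 322 without control 4 and 133 without mimic 4. Of 9219 genes above 10 CPM, 99.4% had a log2 fold change within 0.25 of 0, and the median standard error was 0.108. All 4 mimic libraries lay on one side of all 4 controls for 52 of 11018 genes, or 0.472%, where chance gives 2.86% if libraries are exchangeable. Each group, however, holds 1 library numbered 4, and 5399 of 13014 genes differed between that number and the others. The 19 other splits with 1 such library on each side, counted after seeing the data, gave a median of 0.508% (0.245% to 8.83%).

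Of the gene groups, cytosolic ribosomal proteins had a median log2 fold change of -0.0471 in mimic against control, with 26 of 33 lower. Camera gave adjusted p = 0.016 at a preset correlation and adjusted p = 0.994 with an estimated correlation. The list's mean log2 CPM per library was 8.61 ± 0.0663 in mimic and 8.66 ± 0.122 in control (SD, n = 4 each, exact two-sided permutation p = 0.543). Rps14 had a log2 fold change of -0.17, Rps3 -0.14 and Rps2 -0.14, while Rpl23 had 0.12, and 0 members passed edgeR's threshold over all genes or adjusted over the list alone. The reported miR-155 targets were split evenly, 16 of 32 higher and 16 lower, with a median of 0.000331 (adjusted p = 0.894). Rheb, a GTPase upstream of mTORC1, had a log2 fold change of -0.10, Fos, an immediate-early transcription factor, -0.14 and Carhsp1 -0.07. Nuclear subunits of oxidative phosphorylation (OXPHOS) had a median of -0.0338 (51 of 73 lower, adjusted p = 0.202). The ribosomal call was lost without control 2 (median -0.000205), control 3 (-0.0299) or mimic 1 (-0.0185), with upper-quartile scaling (-0.0359), with limma on log2(TPM + 1) (-0.0177) and with length and GC offsets (-0.0236). It was kept, with a lower median, without control 1 (-0.0792), control 4 (-0.093) or mimic 3 (-0.073). The OXPHOS list passed without control 1 (-0.0588), control 4 (-0.0724) or mimic 3 (-0.0601) and had the opposite sign without control 2 (0.0214) or mimic 1 (0.00258). Within replicate numbers 1 to 3 both lists passed at the preset correlation, and neither with an estimated one, with medians of -0.071 for OXPHOS and -0.09 for ribosomal proteins, while the OXPHOS median was -0.00343 with limma on log2(TPM + 1) and -0.00955 with the offsets, and did not pass in either. The count of lists called, 1 of 23, was 0 without control 2 or control 3, 2 without control 1, mimic 2 or mimic 3, 3 without mimic 4, 4 without mimic 1 and 7 without control 4. It was 4 within replicate numbers 1 to 3 and 3 with number 4 as a batch term.

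The remaining lists did not pass in mimic against control, with adjusted p from 0.202 to 0.991. Mitochondrial groups had medians of 0.00758 for fission and fusion, -0.0126 for biogenesis regulators, -0.0323 for fatty acid oxidation, 0.00347 for the TCA cycle and -0.0055 for mitophagy and autophagy. Metabolic and stress groups had medians of 0.0357 for glycolysis, 0.0286 for hypoxia response, 0.0489 for cholesterol synthesis, 0.000755 for antioxidant response and -0.0384 for integrated stress and unfolded protein response. The medians were 0.0713 for interferon-stimulated genes, -0.000481 for NF-kB and inflammatory genes, -0.00373 for p53 and apoptosis, 0.0147 for cell cycle, 0.0372 for neuronal identity, 0.0378 for the small RNA pathway and -0.0528 for the study axis. Markers of other cells were few and had medians of -0.165 for 5 fibroblast and mesenchymal genes, -0.00297 for 3 glial genes and -0.203 for 3 immune and endothelial genes. For the fission and fusion, TCA cycle, and antioxidant lists the test pointed down over a median above 0, and for NF-kB and p53 genes it pointed up over a median below 0. The list of mitochondrially encoded mRNAs had 0 measured members and is not analysed here.

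The inhibitor was compared with control to ask which genes respond when miR-155 is blocked, and edgeR called 0 of 13014 genes. Tulp4, a tubby-like protein, had the smallest p among the named genes: it measured 35.2 ± 2.02 CPM in inhibitor and 104.7 ± 69.2 in control (SD, n = 4 each), with control libraries between 43.5 and 175.6 CPM, and its log2 fold change was -1.57. Lower means in inhibitor were found for Sorbs3 (log2 fold change -0.44), Cyp4f13, a cytochrome P450 (-0.36), Angptl6, an angiopoietin-like factor (-0.35), Phf19, a Polycomb accessory protein (-0.39), and Matk, a kinase that acts on Src family members (-0.35). Higher means were found for Mmaa, a cobalamin metabolism gene (0.46), Mnd1, a meiotic recombination gene (0.33), Pfkfb1, a regulator of glycolysis (0.27), and Psmd6, a proteasome subunit (0.15). Each of these 10 had an adjusted p of 1 by edgeR.

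In this comparison 67 genes had an unadjusted two-sided p under 0.05 in edgeR, DESeq2 called 1 gene (130 unadjusted) and limma on log2(TPM + 1) called 0 (101). The DESeq2 call, named after its values were seen, was Hsf5, which edgeR's filter left out. It was at 0 in the 4 inhibitor libraries, where 3 counts correspond to 0.0435 to 0.0494 CPM, and at 0.118 to 0.218 CPM in the controls. Within replicate numbers 1 to 3, edgeR called 0 genes (189 unadjusted), and with number 4 as a batch term 0 (180). The unadjusted count was 184 without control 2, 170 without control 4 and 116 without inhibitor 4. The inhibitor and control libraries did not overlap for 49 of 11018 genes, or 0.445%, where chance gives 2.86% for exchangeable libraries and the 19 other splits with 1 number 4 library on each side gave a median of 0.526% (0.227% to 4.39%).

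As a group, nuclear OXPHOS subunits had a median log2 fold change of 0.0246 in inhibitor against control, with 50 of 73 higher. Camera gave adjusted p = 0.00331 at a preset correlation and adjusted p = 0.83 with an estimated correlation. The list's mean log2 CPM per library was 7.07 ± 0.0602 in inhibitor and 7.04 ± 0.104 in control (SD, n = 4 each, exact two-sided permutation p = 0.629). Uqcrb, a complex III subunit, had a log2 fold change of 0.17, Atp5k, an ATP synthase subunit, 0.19, Cox6c, a cytochrome c oxidase subunit, 0.12 and Ndufs1, a complex I subunit, 0.08. None of them passed edgeR's threshold, and 0 list members did when adjusted over the list alone. Cytosolic ribosomal proteins had a median of -0.000132 and a mean of 0.00693 (adjusted p = 0.323). The reported miR-155 targets had a median of -0.0299 (20 of 32 lower, adjusted p = 0.625), with Tab2, a TAK1-binding adaptor, at -0.10. The OXPHOS call was lost without control 1 (median 0.00194) and with length and GC offsets (0.0261), and the sign turned without control 4 (-0.0119) or inhibitor 1 (-0.0123). The call was kept without control 2 (0.0763) and inhibitor 4 (0.0468). The ribosomal median was 0.018 without control 3, 0.00653 without mimic 1, 0.0102 without inhibitor 2 and 0.0126 without inhibitor 4, and without control 2 it was 0.0536 and the list passed. The test pointed up over a median below 0 for the ribosomal and fatty acid oxidation lists, and for interferon-stimulated genes the median was 0.0453 and the mean -0.107. The count of lists called, 1 of 23, was 0 without control 1 or inhibitor 1, 3 without control 2 or inhibitor 2, and 4 without control 4, inhibitor 3 or inhibitor 4. Within replicate numbers 1 to 3 the count was 3 and the OXPHOS list, with a median of 0.0146, did not pass, and with number 4 as a batch term the count was 4. Of the markers of other cells, the 3 glial genes had a median of -0.466 (2 of 3 lower, adjusted p = 0.199), the 5 fibroblast and mesenchymal genes -0.119 (5 of 5 lower, adjusted p = 0.171) and the 3 immune and endothelial genes 0.348 (2 of 3 higher, adjusted p = 0.786). The glial mean log2 CPM was 0.493 ± 0.198 in inhibitor and 0.781 ± 0.0843 in control (SD, n = 4 each). The exact two-sided permutation test of this mean gave p = 0.0286, the smallest that 4 against 4 allows, and an adjusted p of 0.657 over the 23 lists.

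The direct comparison of mimic with inhibitor contrasts reagents meant to add and to block miR-155, and edgeR called 0 of 13014 genes. Slc38a6, an amino acid transporter, came nearest to the threshold among the named genes, with 19.3 ± 1.33 CPM in mimic and 12.7 ± 1.12 in inhibitor (SD, n = 4 each) and a log2 fold change of 0.60. Higher means in mimic were also found for Phactr2 (0.33), Zdhhc1, a palmitoyltransferase (0.37), Atosa (0.27) and Il15ra, the interleukin-15 receptor alpha chain (0.47). Lower means were found for Sri, a calcium-binding protein (-0.32), Atp5g3, a subunit of the ATP synthase ring (-0.20), Mrpl36, a mitochondrial ribosomal protein (-0.19), Tmem86a (-0.34) and Slc39a7, a zinc transporter (-0.23). Each of these 10 had an adjusted p of 1 by edgeR. The axis genes had log2 fold changes of 0.13 for Pparg, -0.06 for Esrra and 0.07 for Dnm1l, and without mimic 4 Pparg was at -0.000349 and Esrra at 0.02. Esrra was lower in mimic than in inhibitor at 4 of 4 replicate numbers. The exact two-sided permutation test between the groups, which took no account of the number, gave p = 0.514 (adjusted p = 0.971).

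An unadjusted two-sided p under 0.05 was reached by 77 genes in edgeR, and the smallest adjusted p was 0.0948, for Gm49378. DESeq2 called 6 genes (131 unadjusted) and limma on log2(TPM + 1) called 0 (114). The DESeq2 calls, named after their values were seen, were Hsf5, Mss51, Gm49378, Gm45062, Tafa4 and Gm45717. Tafa4 was at 0 in the 4 inhibitor libraries, where 3 counts correspond to 0.0435 to 0.0494 CPM, and at or under 0.24 CPM in the others, and Gm45717, which overlaps Ifitm2 on the same strand, stood at 31.1 and 35.7 CPM in mimic 1 and mimic 3 and at or under 1.05 CPM elsewhere, with a sum of both that varied 1.38-fold. Gm49378 passed in edgeR, as 1 gene, without control 2 and in a fit of these 8 libraries alone, with a log2 fold change of -4.04 in both. Within replicate numbers 1 to 3, edgeR called 0 genes (163 unadjusted), with number 4 as a batch term 0 (160), and without mimic 4 the unadjusted count was 126. The mimic and inhibitor libraries did not overlap for 70 of 11018 genes, or 0.635%, where chance gives 2.86% for exchangeable libraries and the 19 other splits with 1 number 4 library on each side gave a median of 0.635% (0.363% to 3.54%).

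Nuclear OXPHOS subunits were lower in mimic than in inhibitor, with a median log2 fold change of -0.0584 and 65 of 73 lower. Camera gave adjusted p = 3.04e-08 at a preset correlation and adjusted p = 0.804 with an estimated correlation. Matched by replicate number after seeing the data, the difference lay mostly at number 1. The list's mean log2 CPM was 6.92 in mimic 1 and 7.15 in inhibitor 1. It was 7.03 and 7.04 at number 2, 7.08 and 7.08 at number 3, and 7.04 and 7.02 at number 4. The exact two-sided permutation test between the groups gave p = 0.314. Cytosolic ribosomal proteins were also lower, with a median of -0.0631 and 29 of 33 lower (camera adjusted p = 2.1e-05, adjusted p = 0.804 with an estimated correlation). Their mean log2 CPM was 8.52 in mimic 1 and 8.74 in inhibitor 1. It was 8.63 and 8.62 at number 2, 8.67 and 8.70 at number 3, and 8.63 and 8.62 at number 4. The exact two-sided permutation test between the groups gave p = 0.286. Among OXPHOS subunits, Cox7a2 had a log2 fold change of -0.15, Ndufb6 -0.16 and Ndufa1 -0.20, and among ribosomal proteins, Rps27a had -0.15, Rpl36 -0.15 and Rplp2 -0.13. In both lists 0 members passed edgeR's threshold over all genes or adjusted over the list alone. The reported miR-155 targets had a median of 0.00664 (adjusted p = 0.485), and Socs1, a cytokine signalling suppressor, had a log2 fold change of 0.20. Without mimic 1 both calls were lost, with an OXPHOS median of -0.034 and a ribosomal median of -0.0296, and without inhibitor 1 the ribosomal call was lost (-0.0272) and the OXPHOS median was -0.0197. At the preset correlation both calls were kept in 3 other alternatives, with medians of -0.0352 for OXPHOS and -0.0287 for ribosomal proteins with length and GC offsets, -0.0278 and -0.0319 with limma on log2(TPM + 1), and -0.0769 and -0.0814 within replicate numbers 1 to 3. With an estimated correlation 0 lists were called in any of the comparisons in these 3 alternatives, as in the fits without 1 library, a check added after seeing the data. The count of lists called, 2 of 23, was 0 without mimic 1, 1 without inhibitor 1, 6 without mimic 4 and 7 without inhibitor 4, and it was 5 within replicate numbers 1 to 3 and 4 with number 4 as a batch term. Fry, which tests whether the genes of a list move on balance one way, called 0 lists in each of the 3 comparisons, as did camera with an estimated correlation, where camera at the preset correlation had 3, 5 and 4 lists at an unadjusted p under 0.05. Marker lists had medians of 0.32 for glial (adjusted p = 0.425), 0.121 for fibroblast and mesenchymal (adjusted p = 0.653) and 0.0354 for immune and endothelial genes (adjusted p = 0.732). Median and mean differed in sign for the biogenesis (0.0297 and -0.0177), fatty acid oxidation (-0.0332 and 0.00765), glycolysis (-0.00286 and 0.0013) and immune and endothelial lists (0.0354 and -0.269).

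Opposite responses to mimic and inhibitor were looked for among genes called against control by both, and edgeR found 0 such genes (71 and 67 genes at an unadjusted p under 0.05). DESeq2 calls of both comparisons shared 0 genes of opposite sign. Across the 9219 genes above 10 CPM, which are not independent replicates, the log2 fold changes of the reagents had a correlation of 0.354 and a covariance of 0.0038, and 67.4% of genes had the same sign. Unchanged groups simulated against the same controls gave a mean correlation of 0.0949 (-0.0159 to 0.258 in 20 simulations), a covariance of 0.00156 and 50.2% of the same sign. That simulation left out the chance in the controls themselves, and one with the controls drawn too, added after the first value was seen, gave 0.485 (0.384 to 0.545), 0.0136 and 66.4%. In both, the simulated libraries lacked the differences by replicate number that the real groups share, so neither gives the value to be met without a response. With the controls split between the comparisons, the correlation ran from -0.662 to -0.319 and the covariance from -0.0274 to -0.00652. Neither a shared nor an opposed response to the reagents can be read from these values.

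Genes with a miR-155-5p seed site in the 3' UTR were compared with genes without one, since transcripts with such sites are the ones the microRNA can bind. In mimic against control the 401 genes with an 8mer site (AGCATTAA) had a median log2 fold change 0.0152 above that of 11113 genes without a site, and 45.6% of them were lower in mimic against 54.6% of genes without a site. The shift was -0.0174 in a single simulation with no site gene changed and genes drawn independently, which does not show its spread in real libraries. The shifts for 7mer-m8 and 7mer-A1 genes were 0.0135 and 0.0196. In inhibitor against control the 8mer shift was -0.00577, and in mimic against inhibitor it was 0.0197. By camera at the preset correlation the 8mer genes had p = 0.27, p = 0.648 and p = 0.116 in these comparisons (p = 0.671, p = 0.86 and p = 0.548 with an estimated correlation), and exact two-sided permutation tests of the per-library site score gave an adjusted p = 0.943 for each kind of site in each comparison. Of the 7mer tests, unlike the exact permutation tests, camera passed 0.05 for 7mer-A1 in mimic against control (p = 0.036, and p = 0.393 with an estimated correlation) and for 7mer-m8 in mimic against inhibitor (shift 0.0232, p = 0.0311, and p = 0.479 with an estimated correlation), both toward higher levels in mimic. The 95% interval of the per-library score difference between mimic and inhibitor was -0.0605 to 0.0828, or 0.959-fold to 1.06-fold. Against control it was wider, -0.141 to 0.2 for mimic (0.907-fold to 1.15-fold) and -0.145 to 0.181 for inhibitor (0.904-fold to 1.13-fold). Of 419 other 7-mers of the same base content, 112 had a lower shift than AGCATTA in mimic against control, 39 in inhibitor against control and 259 in mimic against inhibitor. Their shifts ran from -0.000638 to 0.0301, from -0.0198 to 0.0046 and from 0.00227 to 0.032 in the same order. In mimic against inhibitor all of them were thus above 0, so a shift toward higher levels in mimic was not particular to AGCATTA. The sign depended on single libraries: in mimic against control the shift was -0.0345 without control 2, 0.0464 without control 1 and 0.0638 without control 4, and camera at the preset correlation passed 0.05 in each of these fits, which it did not with all libraries. In inhibitor against control it was -0.0692 without control 2, where camera passed 0.05, 0.0193 without control 1, 0.0359 without control 4 and 0.00548 without inhibitor 1. Within replicate numbers 1 to 3 the shifts were 0.0604, past 0.05 by camera, and 0.0214, and with length and GC offsets the mimic value was -0.00201.

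**Figure D2:**
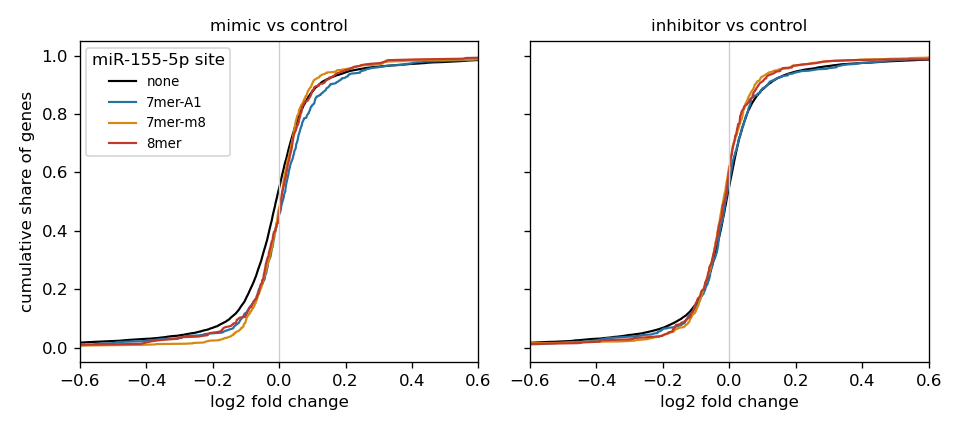
Cumulative share of genes (vertical axis) by log2 fold change (horizontal axis) for genes with an 8mer, 7mer-m8, 7mer-A1 or no miR-155-5p site, in mimic against control and inhibitor against control. The 8mer curve crosses the curve of genes without a site in both panels, and their medians differ by 0.0152 and -0.00577.

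Hypoxia-response genes differed by replicate number in each transfection group; the members named were chosen after their values were seen. Adm, which encodes the peptide adrenomedullin, measured 42.8 ± 1.06 CPM in the 3 libraries numbered 4 (SD, n = 3, 1 from each group) and 1.63 ± 0.491 in the other 9 (SD, n = 9). Slc2a1, a glucose transporter, was 5.13-fold higher in the number 4 libraries, Bnip3, a mitophagy receptor, 4.85-fold, Pdk1, a pyruvate dehydrogenase kinase, 5.3-fold and Ankrd37 8-fold. With group in the model, 18 of the 20 measured members of the list rose in number 4 by edgeR, Pfkfb3 fell and Car9 did not pass (list median log2 fold change 1.01; camera adjusted p = 1.27e-61, adjusted p = 3.86e-05 with an estimated correlation). Comparing each number with the others in this way, a choice made after seeing the data, edgeR called 71, 28, 421 and 5399 genes for numbers 1, 2, 3 and 4. The libraries numbered 4 are among the others in the first 3 of these comparisons. No label names a hypoxia treatment for these libraries or says what a number stands for. The first principal component, 28.4% of the variance, ran from 40.1 to 41.6 in the number 4 libraries and from -23.5 to -4.6 in the others.

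**Figure D3:**
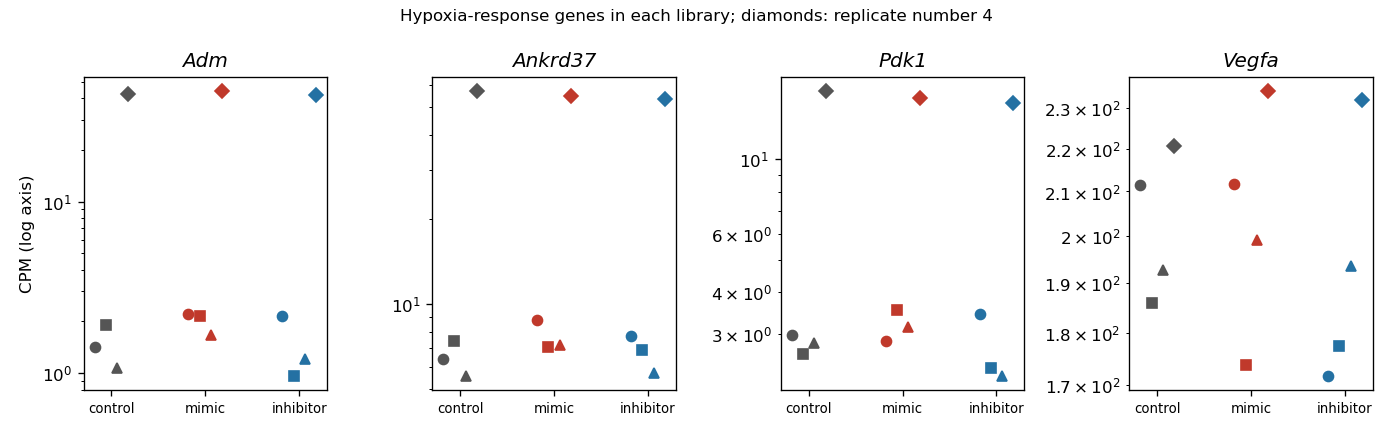
CPM (vertical log axis, scaled per panel) of Adm, Ankrd37, Pdk1 and Vegfa, chosen after their values were seen, in each library of the control, mimic and inhibitor groups; circles, squares, triangles and diamonds are replicate numbers 1, 2, 3 and 4. The 3 diamonds are the highest values in each panel, from 41.9 to 44 CPM for Adm against 0.958 to 2.2 CPM in the other 9 libraries.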

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

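The comparison of libraries by replicate number, and the tests of what lies behind it, were chosen only after the result was seen. Of 111 sets of 4 values examined, 8 had a library set apart from the other 3 by Dixon's gap ratio, and chance gives about 1 in 20. The hypoxia list's mean log2 CPM was 6.22 in control 4 against 4.81 to 4.87 in the other controls, 6.33 in mimic 4 against 4.94 to 4.99, and 6.31 in inhibitor 4 against 4.83 to 4.91. Pfkfb1 stood at 4.77 CPM in control 4 against 5.45 to 5.54 in the other controls, and at 5.19 CPM in mimic 4 against 5.96 to 6.1. Dnm1l measured 62.5 CPM in mimic 3 against 76.1 to 77.4 in the other mimic libraries. Necab2 measured 2.97 CPM in mimic 3 against 2.55 to 2.6. Slc38a6 measured 17.3 CPM in mimic 1 against 19.7 to 20.2.

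The hypoxia-response genes were higher in the number 4 library of each group, with a list median of 1.01 on the log2 scale. The median stayed at 1.01 after thinning each library to the smallest total. Thinning leaves expected CPM unchanged, so this value could not test depth. Depth as the whole cause is argued against by the total counts. They were 68734250 in control 4, 62389350 in mimic 4 and 65233809 in inhibitor 4, and ran from 60695388 to 74200532 in the other libraries. A gene length and GC trend as the whole cause is argued against by a median of 0.974 with offsets. Of the 18 members that rose, 0 overlap a listed gene on the same strand. Of 11 measured markers of other cells, with means of at most 14.7 CPM in number 4, 2 rose, while 2650 of all 13014 genes rose. By type, 1 of 5 fibroblast and mesenchymal, 0 of 3 glial and 1 of 3 immune and endothelial markers rose. The bound set beforehand for cells of another type was a rise of most markers. Cells of a single type would raise only their own few markers, so the count cannot exclude them. A culture with less oxygen, a denser culture or another day of work for number 4 may account for the pattern, and these cannot be told apart because no label says what the number marks. No biological explanation from the design was tested, since each transfection group holds 1 library of each number.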

How the results depend on the processing

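Replicate numbers 1 to 3 alone, number 4 as a batch term, the fit without switch genes, and the length and GC offsets were chosen only after the result was seen. Genes called in mimic against control, inhibitor against control and mimic against inhibitor, 0 each in edgeR, were 3, 1 and 6 with DESeq2 and 1 for mimic against inhibitor in the fit of 8 libraries. They were 0 to 1, 0 and 0 to 1 with each library left out. Lists called, 1, 1 and 2, were 0 for mimic against control with upper-quartile scaling, limma at either pseudocount or an adjusted p under 0.01, and 0, 0 and 0 with an estimated correlation or fry. They were 4, 3 and 5 with numbers 1 to 3, 3, 4 and 4 with number 4 as a batch term, and 0 and 0 for the comparisons with control under length and GC offsets. Leaving out each library gave 0 to 7, 0 to 4 and 0 to 7. The 8mer shift ran from -0.0345 to 0.0638 for mimic and from -0.0692 to 0.0359 for inhibitor with each library left out. It was 0.0604 and 0.0214 with numbers 1 to 3, and -0.00201 for mimic with the offsets. The ribosomal median in inhibitor against control, -0.000132, was 0.00788 with RLE, 0.0103 with upper-quartile scaling, 0.000591 with the 1 CPM filter, 0.00777 with DESeq2 and 0.00197 with the offsets, and ran from -0.0441 to 0.0536 with each library left out. The OXPHOS median ran from -0.0724 to 0.0214 for mimic and from -0.0123 to 0.0763 for inhibitor against control. Dnm1l in mimic against control was at -0.00144 with the offsets. With each library left out, log2 fold changes ran from -0.19 to 0.047 for Pparg and -0.15 to 0.12 for Dnm1l in mimic against control. In inhibitor against control they ran from -0.20 to 0.049 for Esrra and -0.22 to 0.051 for Dnm1l. In mimic against inhibitor they ran from -0.000349 to 0.29 for Pparg and -0.14 to 0.0165 for Esrra. Of 1092 values of named genes under alternatives, 1078 kept their direction and side of the threshold and 14 reversed, all of them of Pparg, Esrra or Dnm1l. The other named genes had been chosen because their groups did not overlap, which favours a kept direction. The 1078 values are therefore no measure of robustness. The cause of the changes under alternatives was not tested.

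With the replicate number as a block, 0 genes were called in each comparison by edgeR, and lists called were 4, 4 and 3. Same-numbered libraries had deviations correlated above 0.1 in 7 of 12 pairs (-0.0709 to 0.526, and 0.444 to 0.526 for number 4), so the numbers were not taken as pairing the samples. Against this choice, 9 of 12 libraries correlated best with one of their own number, and 10 of 12 were nearest to one of it. All 12 were nearest to a library of another group. The chi-square per degree of freedom was 5.57 to 44.6 between same-numbered libraries and 10.9 to 103 within groups. The fit with group as its only term counts differences by number as spread, which can hide differences between groups. Depth limits genes such as Ppargc1a, at 0 counts in 11 libraries.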

Other observations

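The comparison by replicate number, the definition of switch genes, the test of the group as their whole cause, the permutation test of the gap between OXPHOS and matched genes and the count of unadjusted p over other splits were chosen only after the result was seen. In the number 4 libraries, named genes being list members of smallest p, genes of glycolysis rose together (15 of 16 higher, median log2 fold change 0.588; camera adjusted p = 8.66e-20, adjusted p = 0.198 with an estimated correlation). Aldoc, a neural aldolase, was 4.12-fold higher, Eno2, the neuronal enolase, 2.78-fold and Pgk1, a phosphoglycerate kinase, 1.74-fold. Genes of cholesterol synthesis also rose (21 of 23 higher, median 0.971; camera adjusted p = 8.35e-37, adjusted p = 0.0598 with an estimated correlation), with Hmgcs1 at 4.07-fold and Msmo1 at 2.41-fold. Lists other than these and the hypoxia list did not pass (adjusted p from 0.0652 to 0.986). Of 30 cell cycle genes, 15 rose and 5 fell (median 0.213, adjusted p = 0.147), with Cenpf at 2.7-fold, Mki67 at 2.13-fold, Top2a at 1.49-fold and Tyms at 0.723-fold. Of 26 integrated stress and unfolded protein response genes, 5 rose and 10 fell (median -0.0238, adjusted p = 0.0652), with Ppp1r15a at 0.33-fold, Atf3 at 0.435-fold, Chac1 at 0.572-fold and Sesn2 at 0.59-fold. Of 22 neuronal identity genes, 8 rose and 6 fell (median 0.0579, adjusted p = 0.73), with Mapt at 1.4-fold, Nefh at 1.38-fold and Gata3 at 0.6-fold.

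A set of 31 genes, of 10502 with a highest level above 5 CPM, was present in some libraries and more than 30-fold lower in others without following a group, as judged by the midpoint between 0 and their highest level. Gemin4 stood at 50.8 to 61.1 CPM in control 2, mimic 1, mimic 3, inhibitor 1 and inhibitor 3 and at or under 0.476 CPM in the other 7, and its same-strand neighbour Glod4 stood at 50.4 to 54 CPM in those 5 and at 102.2 to 113.1 in the other 7, with the sum of both varying 1.1-fold. Of the 31 genes, 74.2% overlap a listed gene on the same strand, against 4.42% of other genes (odds ratio 62, 95% interval 26.6 to 161; Fisher's exact p = 6.77e-25, two-sided), which is consistent with reads going to one of 2 overlapping genes in some libraries and to the other in the rest. Of these 23 genes, 16 had levels opposed to a partner's (correlation under -0.5) and 20 a sum with it that varied under 2-fold. The partner taken was the one of lowest correlation in these data, which favours opposed levels, and Gm49388 and Hsd3b7 are each other's partner. A steady sum also came without opposed levels, as for Gp1bb with Septin5 (correlation -0.38, sum 1.2-fold). The sum varied 45.1-fold for Gm42878 with Adam1a, 16.8-fold for Gm44503 with Dnaaf4 and 4.43-fold for Gm44502 with Cpt1b. The transfection group as the whole cause is argued against, since 31 of the 31 genes had libraries of 1 group on both sides of their midpoint, which leaves a part from the group open, and of the 8 genes without such a neighbour Adm follows the number 4 libraries, while the other 7 (Guca1a, Ilk, Jmjd8, Pus3, Rps18-ps6, Sp6 and 1 without a symbol) stay open.

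OXPHOS genes were lower in mimic than in inhibitor by a median of -0.0584. The number 4 libraries are argued against by a median of -0.0769 in numbers 1 to 3 (camera p = 0.205 with an estimated correlation). Within those numbers the difference lay mostly at number 1, where the list's mean log2 CPM was 6.92 in mimic and 7.15 in inhibitor. A shift of short abundant mRNAs in general stays open. The median lay at percentile 0 of 10000 random lists matched on expression, length and GC (-0.0332 to -0.00832). However, such lists vary too little to judge members with an estimated correlation of 0.425, and ribosomal genes were lower too (-0.0631). The gap between members and matched genes differed by -0.0352 between the groups (exact two-sided permutation p = 0.229). With length and GC offsets the median was also -0.0352, between the bounds set for and against such a trend, so a part from it cannot be told apart from the group difference. Chance could not be excluded, since 6 of the 35 splits of these 8 libraries gave a list p as small, the smallest other being 4.53e-13 against 1.32e-09. An effect of the reagents stays open, as untested beyond these libraries.

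Other splits of the 8 libraries of each comparison do not exclude chance for the lists called, the 8mer shifts or the genes at an unadjusted p under 0.05. For genes called they decide nothing, since a real count of 0 is met by 35 of 35 splits, and the highest other counts were 1, 1276 and 1 for mimic against control, inhibitor against control and mimic against inhibitor. The split with 1276 genes put controls 1 and 4 and inhibitors 2 and 4 against the rest, which points to a structure of the samples. The other 14 of the 15 splits with both number 4 libraries on one side called at most 2 genes, so the number alone does not account for that count, although such splits had 492 to 4376 genes at an unadjusted p under 0.05 against 67 to 1085 in those with the number 4 libraries apart. With numbers 1 to 3 alone the inhibitor comparison called 0 genes. For genes at an unadjusted p under 0.05, 32, 35 and 23 of 35 splits gave as many as the real 71, 67 and 77, with 3583, 4376 and 1625 at most in the others. For lists called, 33, 29 and 28 of 35 splits gave as many as the real 1, 1 and 2, with 9, 9 and 6 at most in the others. For the 8mer shift, 30 of 35 splits were as large as 0.0152 in mimic against control (highest other 0.137) and 34 of 35 as large as -0.00577 in inhibitor against control (0.151).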
